A study of Dictyostelium discoideum with 18 samples.

How the data were processed

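RNA of Dictyostelium discoideum AX3, a laboratory strain kept as vegetative cells, was measured in 18 MACE-seq libraries, an assay that sequences a tag near the 3′ end of polyadenylated transcripts. Per the labels, cells grew in HL5 medium with 100 mM glucose at 22 °C and 180 rpm, and 100 ng of RNA entered each library. The 6 groups of 3 libraries were normoxia at t0, hypoxia at 1% O2 for 1, 5 and 24 h, and reoxygenation for 1 and 5 h after 24 h of hypoxia. The oxygen level after reoxygenation is given as 21% in the characteristics and as 20% in the treatment protocol. The t0 cells came from the culture tube, and the labels name no culture kept at normoxia for the same time. The replicates are not stated to come from separate cultures, so every p-value below measures only the spread between these samples. The proteomic part named in the design was not analysed here.

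The deposited table holds raw counts for 13731 genes, of which 13413 had at least 1 count and 318 had none in any library. The deposited columns headed tpm hold CPM, the count scaled by its column total, to which each value was equal within 5.5e-12 CPM. Other deposited columns hold a signal, which is the count divided by 1 factor per library, and means of the counts per group. The authors also deposited log2 fold changes against t0, each with a p-value and an FDR. The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.4.4, HTSeq 2.0.2 and DESeq2 1.38, and the design text states that alignment and the comparisons with t0 were made by a sequencing company. The genome build, the annotation release, the strand setting and any removal of duplicate tags are not given in the sources used here, nor is the handling of tags that match several genes. Of the gene identifiers, 13729 were matched to a reference table of symbols, and 4091 genes had a symbol other than their identifier.

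Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr on the groups, which left 10289 genes, and libraries were scaled by TMM factors. All 18 libraries entered 1 quasi-likelihood model with a term per group and no replicate block, since the replicate numbers are not stated to pair libraries across groups. The common biological coefficient of variation was 0.205. For 7 comparisons, namely each hypoxia and reoxygenation group against t0 and both reoxygenation groups against hypoxia 24 h, each gene was tested by the edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment over the 10289 genes. A gene is called changed at an adjusted p under 0.05 with no fold minimum, and the number that also changed at least 2-fold is given beside it. A further F test asked whether a gene differed anywhere among the 6 groups. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of F. CPM values in the text use TMM-scaled totals, and group values are means over 3 libraries.

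The groups, comparisons, tests, the rule for named genes, 41 gene lists and most alternatives were fixed before the data were examined. The lists were defined by gene symbols or product names and cover oxygen-linked genes, energy metabolism, translation, protein turnover, the cell cycle, redox enzymes, lipid synthesis, iron and heme, lysosomes, development, the cytoskeleton, transporters and secondary metabolism. After the table was opened and before any test, it was settled that product names be matched without regard to case and without the word signal. Of the lists, 40 had at least 5 tested members and were tested with camera from limma 3.58.1 on log CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and the rotation test fry were run beside it, of which fry asks only whether members move in 1 direction on balance and does not compare them with other genes. Counts of changed members are given over all genes tested and adjusted over the list alone.

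The text names genes from a set fixed by a rule. Not all of the set is printed, and the list members printed as examples were picked from it after their values were seen. The rule takes every measured member of the oxygen panel. In each comparison it takes the 4 largest rises and 4 largest falls among called genes with a symbol, replicates that do not overlap between the groups and at least 10 CPM in the higher group. For hypoxia 5 h and 24 h against t0 and reoxygenation 5 h against hypoxia 24 h, it takes up to 3 members with the smallest adjusted p of each list called by camera and up to 2 of any other list used as an example. For each comparison it adds, under the same conditions, the gene without a symbol that has the largest change. By chance, the replicates of 2 groups of 3 fail to overlap for 10% of unchanged genes.

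Library totals ranged from 4458018 to 10993722 counts, and intervals on single counts or shares cover counting error only. In simulations at the depth and spread found here, 70 to 79 of 100 genes changed 2-fold and 98 to 100 of 100 changed 4-fold were recovered per comparison. There were 6 to 19 calls among 9846 to 9901 unchanged genes, the 19 beside 75 and 99 recovered at reoxygenation 5 h against hypoxia 24 h. Fewer genes changed there than the 45.6% called at hypoxia 24 h against t0, and no rate was taken at low counts.

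Other settings chosen in advance were RLE size factors, no filter on low counts, a stricter filter of 10 counts in every library of at least 1 group, a minimum change of 2-fold, DESeq2 1.42.0 in place of edgeR, a replicate block, fits of only the 6 libraries compared, and leaving out each replicate number or library in turn. Scaling by total counts alone, list tests without each library and named genes without each library were chosen after seeing the data. The correlation that comes from shared t0 libraries was examined in 20 simulations, and other groupings of the libraries in 10 splits per comparison or 100 regroupings. Figures and intervals were made with Python 3.11.15, matplotlib 3.10.9, scipy 1.17.1 and numpy 2.4.6.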

Results

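Transcripts of vegetative Dictyostelium cells were counted in 18 libraries in the 6 groups of 3 given above.

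Across the 6 groups, 7356 of 10289 tested genes differed (71.5%, edgeR quasi-likelihood F test with Benjamini-Hochberg adjustment, n = 3 per group). This test answers whether a transcript differed anywhere among the groups, and not what made it differ. The first principal component held 54.6% of the variance in log CPM, the second 12.5% and the third 9.3%. rabR, which encodes a Rab GTPase of vesicle traffic, averaged 0.863 CPM at t0, 362, 201 and 395 CPM at 1, 5 and 24 h of hypoxia, and 1.5 and 0.854 CPM at 1 and 5 h of reoxygenation. cxgS and cxgE encode alternative isoforms of cytochrome c oxidase subunit VII. In the same order of groups, cxgS averaged 103, 415, 718, 578, 265 and 15.0 CPM, and cxgE 200, 188, 23.6, 42.5, 95.2 and 249 CPM.

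**Figure D1:**
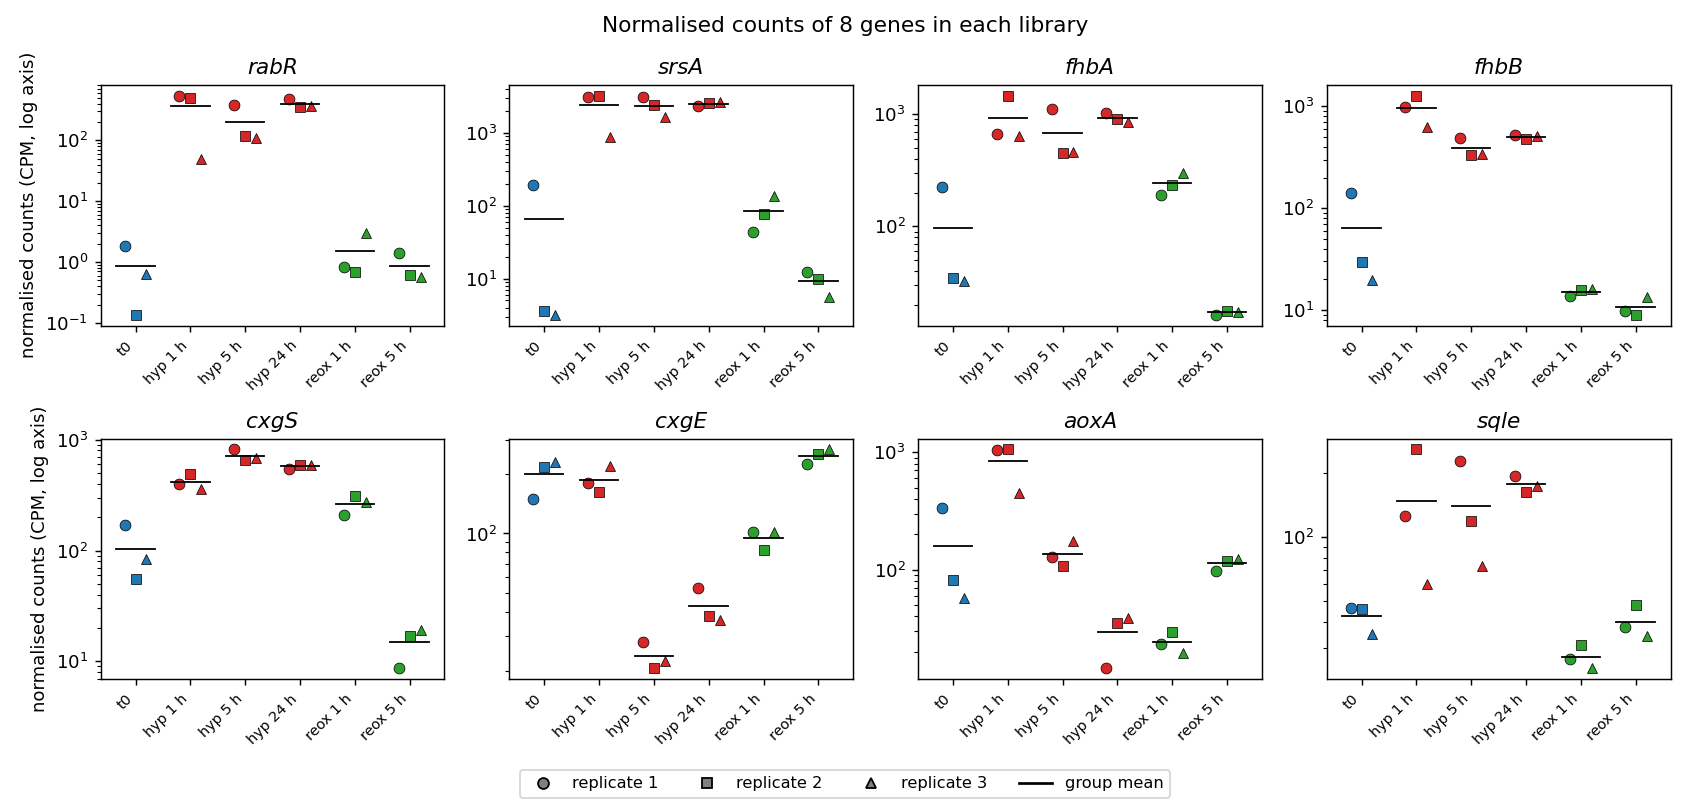
Levels of rabR, srsA, fhbA, fhbB, cxgS, cxgE, aoxA and sqle in each of the 18 libraries, in CPM on a log axis. Blue marks t0, red hypoxia and green reoxygenation. Circles, squares and triangles are replicates 1, 2 and 3, and each black line is the mean of 3 libraries.

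The first question was what changes within 1 h of low oxygen, asked by hypoxia 1 h against t0 (n = 3 per group, values after ± are SE). The largest rises among named genes with a symbol were rabR (DDB_G0271980, 362 against 0.863 CPM, log2 fold change 8.53 ± 0.93, edgeR adjusted p = 1.75e-06), srsA (DDB_G0289521, 2380 against 66.3 CPM, 5.15 ± 1.08, adjusted p = 0.00126), annotated as a starvation responsive small protein, and abcG21 (DDB_G0269206, 80.9 against 2.52 CPM, 5.01 ± 0.35, adjusted p = 4.68e-08), an ABC transporter. Both flavohemoglobin genes rose, whose products detoxify nitric oxide, namely fhbB (DDB_G0292380, 963 against 63.6 CPM, log2 fold change 3.91 ± 0.52, edgeR adjusted p = 1.42e-05) and fhbA (DDB_G0292378, 922 against 96.8 CPM, 3.24 ± 0.59, adjusted p = 0.000355). Also higher were aoxA (DDB_G0280819, 845 against 158 CPM, log2 fold change 2.41 ± 0.51, edgeR adjusted p = 0.0014), the alternative oxidase that passes electrons to oxygen without cytochrome c oxidase, cxgS (DDB_G0277839, 415 against 103 CPM, 2.01 ± 0.32, adjusted p = 9.01e-05) and CYP515B1 (DDB_G0282283, 21.4 against 1.16 CPM, 4.15 ± 0.33, adjusted p = 1.21e-07), a cytochrome P450. The gene without a symbol that changed most was DDB_G0290839 (56.1 against 0.543 CPM, log2 fold change 6.66 ± 0.98, edgeR adjusted p = 4.51e-05). The largest falls were abcG22 (DDB_G0270826, 2.17 against 61.1 CPM, log2 fold change -4.70 ± 0.28, edgeR adjusted p = 1.97e-08), lmpB (DDB_G0287035, 8.37 against 155 CPM, -4.12 ± 0.34, adjusted p = 1.46e-07), a lysosomal membrane protein, fslB (DDB_G0270730, 3 against 45.5 CPM, -3.81 ± 0.34, adjusted p = 2.38e-07), a frizzled and smoothened-like receptor, and samkB (DDB_G0284859, 0.316 against 12.7 CPM, -5.08 ± 0.90, adjusted p = 0.000273). Without t0 replicate 1, where these genes stood higher than in replicates 2 and 3, the log2 fold change was 9.78 for rabR, 9.46 for srsA, 5.29 for fhbB, 4.77 for fhbA and 3.60 for aoxA. fslB stood at -4.56 without hypoxia 1 h replicate 3, and samkB at -4.31 without hypoxia 1 h replicate 1. All 7 samkB counts at hypoxia 1 h lay in replicate 3, without which the group held 0 counts and the fall has no exact size.

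In t0 replicate 1 against replicates 2 and 3, srsA measured 192 against 3.54 and 3.19 CPM, fhbA 223 against 35.0 and 32.0 CPM, fhbB 142 against 29.3 and 19.7 CPM, and aoxA 336 against 81.6 and 57.7 CPM. At hypoxia 1 h, replicate 3 was lower than replicates 1 and 2 for rabR, at 50.0 against 537 and 499 CPM, and for srsA, at 862 against 3070 and 3207 CPM. Of the oxygen panel, 4 of 11 members rose and 0 fell after 1 h, 4 and 1 adjusted over the list alone. The panel as a whole was not called, and its median of -0.03 differed in sign from its mean of 0.87 (camera adjusted p = 0.338 upward). At this time cxgE (DDB_G0277837, 188 against 200 CPM, log2 fold change -0.09 ± 0.19, edgeR adjusted p = 0.763) did not pass, nor did phyA (DDB_G0277759, 6.74 against 11.6 CPM, -0.82 ± 0.32, adjusted p = 0.0583), the prolyl hydroxylase that modifies Skp1. phyA passed without hypoxia 1 h replicate 2 (-0.99, edgeR adjusted p = 0.0434) or without t0 replicate 3 (-1.05, edgeR adjusted p = 0.0235).

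Genes of ribosome biogenesis rose at 1 h, with 46 of 49 members higher and 0 lower (46 and 0 adjusted over the list alone). The median log2 fold change was 1.91 (camera adjusted p = 1e-31, adjusted p = 0.297 with an estimated correlation). Aminoacyl-tRNA synthetases, which charge tRNAs for translation, had 26 of 40 members higher and 0 lower (29 and 0 adjusted over the list alone). The median was 0.59 (camera adjusted p = 8.91e-09, adjusted p = 0.297 with an estimated correlation). Genes of pyruvate dehydrogenase and TCA cycle had 19 of 29 members higher and 1 lower (20 and 1 adjusted over the list alone). The median was 0.53 (camera adjusted p = 3.82e-06, adjusted p = 0.297 with an estimated correlation). Complexes II to IV and cytochrome c had 10 of 17 members higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.61 (camera adjusted p = 0.000363, adjusted p = 0.297 with an estimated correlation). Mitochondrial ribosomal proteins had 10 of 11 members higher and 0 lower (11 and 0 adjusted over the list alone). The median was 0.77 (camera adjusted p = 5.42e-05, adjusted p = 0.297 with an estimated correlation).

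At 1 h, glycolysis, a list that also holds the gluconeogenic gene fbp, had 8 of 14 members higher and 0 lower (9 and 1 adjusted over the list alone). The median was 0.54 (camera adjusted p = 0.00274, adjusted p = 0.297 with an estimated correlation). Higher medians were also found for mitochondrial carriers at 0.62 (camera adjusted p = 0.011, adjusted p = 0.297 with an estimated correlation) and iron and heme at 0.44 (camera adjusted p = 0.00783, adjusted p = 0.331 with an estimated correlation). Aggregation genes, which serve cAMP signalling and adhesion in early development, had 0 of 20 members higher and 7 lower (0 and 7 adjusted over the list alone). The median was -0.55 (camera adjusted p = 0.00783, adjusted p = 0.331 with an estimated correlation).

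In all, 3208 of 10289 genes changed at 1 h, 1750 higher and 1458 lower, and 1687 of them at least 2-fold (edgeR adjusted p under 0.05). Under scaling by total counts, 39.7% of called genes were higher in place of 54.6%, and the median of all genes shifted by -0.17. Camera called 17 of 40 lists, 16 higher and 1 lower. No list call in any of the 7 comparisons held with an estimated correlation. Wrong groupings of the 6 libraries called up to 17 lists in a fit of these libraries alone, against 18 for the real grouping. Calls lost without t0 replicate 1 were complex I (camera adjusted p = 0.112), ATP synthase (0.0689) and cytosolic ribosomal proteins (0.112). Without hypoxia 1 h replicate 1, calls were lost for complex I (camera adjusted p = 0.052). Lost with total-count scaling were complex I (camera adjusted p = 0.0792), ATP synthase (0.0861), proteasome (0.211), antioxidant enzymes (0.0505) and fatty acid oxidation (0.0861). Calls lost without hypoxia 1 h replicate 2 were ATP synthase (camera adjusted p = 0.0684), antioxidant enzymes (0.0739) and fatty acid oxidation (0.0586). Without t0 replicate 3, calls were lost for cytosolic ribosomal proteins (camera adjusted p = 0.064), proteasome (0.0563) and fatty acid oxidation (0.0588). The median crossed 0 without hypoxia 1 h replicate 2 for cytosolic ribosomal proteins (median -0.01, camera adjusted p = 0.874). With total-count scaling, medians near 0 crossed it along with the shift of all genes for cytosolic ribosomal proteins (median -0.02, camera adjusted p = 0.375).

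**Figure D2:**
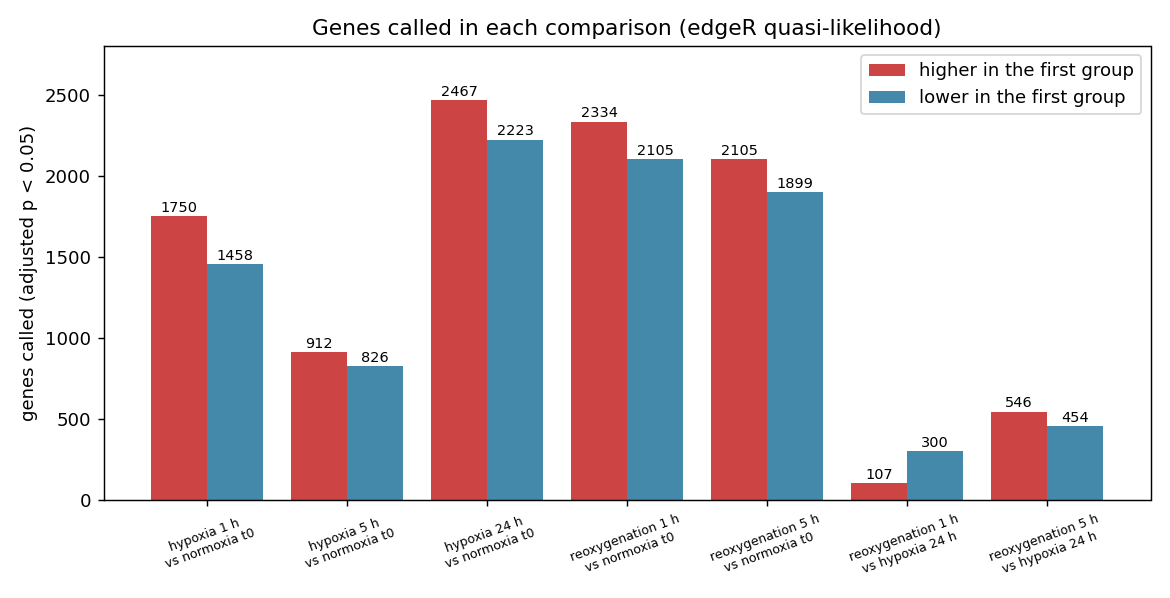
Genes called higher and lower in each of the 7 comparisons by edgeR at an adjusted p under 0.05, n = 3 per group. Numbers on the bars are counts of genes. With scaling by total counts the share of higher genes changed from 54.6% to 39.7% at hypoxia 1 h, and from 26.3% to 55.8% at reoxygenation 1 h against hypoxia 24 h.

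Hypoxia 5 h against t0 asked which changes were present after several hours of low oxygen (n = 3 per group). The cytochrome c oxidase isoforms changed in opposite directions, with cxgE (23.6 against 200 CPM, log2 fold change -3.08 ± 0.21, edgeR adjusted p = 1.55e-07) lower and cxgS (718 against 103 CPM, 2.80 ± 0.33, adjusted p = 2.73e-05) higher. Other large rises were rabR (log2 fold change 7.69 ± 0.91, edgeR adjusted p = 2.97e-05), srsA (5.14 ± 1.08, adjusted p = 0.00322), and the nearly identical copies ddo-1 (DDB_G0273783, 59.9 against 0.977 CPM, 5.71 ± 0.78, adjusted p = 9.07e-05) and ddo-2 (DDB_G0273291, 5.61 ± 0.68, adjusted p = 3.25e-05), annotated as D-aspartate oxidase. Flavohemoglobin genes remained higher, namely fhbA (log2 fold change 2.80 ± 0.58, edgeR adjusted p = 0.00294) and fhbB (2.60 ± 0.49, adjusted p = 0.00145). The alternative oxidase gene aoxA (log2 fold change -0.22 ± 0.49, edgeR adjusted p = 0.807) did not pass. Without a symbol, DDB_G0290839 (log2 fold change 6.49 ± 0.98, edgeR adjusted p = 0.000246) changed most. The log2 fold change was 8.94 for rabR, 9.45 for srsA, 8.14 for ddo-1, 4.33 for fhbA and 3.99 for fhbB without t0 replicate 1. Without hypoxia 5 h replicate 1 it was 6.86 for rabR and 5.23 for DDB_G0290839.

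The largest falls at 5 h were samkB (log2 fold change -4.72 ± 0.83, edgeR adjusted p = 0.000824), p80 (DDB_G0287297, 23.3 against 382 CPM, -4.04 ± 0.44, adjusted p = 1.58e-05), an endosomal membrane protein, ctnC (DDB_G0276479, 11 against 134 CPM, -3.61 ± 0.36, adjusted p = 9.14e-06) and smlA (DDB_G0287587, 64.6 against 715 CPM, -3.47 ± 0.24, adjusted p = 1.93e-07), a regulator of group size. p80 stood at -4.65 without hypoxia 5 h replicate 3. The aldehyde dehydrogenase gene hydA (DDB_G0290479, log2 fold change -1.51 ± 0.21, edgeR adjusted p = 0.000115) fell too. sodE (DDB_G0290343, 105 against 34.9 CPM, log2 fold change 1.58 ± 0.22, edgeR adjusted p = 0.000126), a superoxide dismutase, was higher, as were the lysozyme copies alyD-1 (DDB_G0273197, 4.64 ± 0.36, adjusted p = 6.66e-07) and alyD-2 (DDB_G0273731, 4.81 ± 0.40, adjusted p = 1.4e-06). Of the oxygen panel, 3 of 11 members rose and 2 fell, the same over the list alone, and its median of -0.22 differed in sign from its mean of 0.26 (camera adjusted p = 0.903 upward). phyA (log2 fold change -1.06 ± 0.31, edgeR adjusted p = 0.0271) was called, but its edgeR adjusted p was 0.0543 to 0.145 without any 1 of the 6 libraries compared except t0 replicate 3.

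At 5 h, ribosome biogenesis still had 38 of 49 members higher and 0 lower (43 and 0 adjusted over the list alone). The median was 0.93 (camera adjusted p = 4.97e-20, adjusted p = 0.257 with an estimated correlation). Examples were utp14 (DDB_G0279371, log2 fold change 1.29 ± 0.19, edgeR adjusted p = 0.000204), a processing factor of ribosomal RNA, rpa2 (DDB_G0293560, 1.30 ± 0.21, adjusted p = 0.000409), a subunit of RNA polymerase I, and nog1 (DDB_G0285465, 0.83 ± 0.13, adjusted p = 0.000437). tRNA synthetases had 16 of 40 members higher and 0 lower (19 and 0 adjusted over the list alone). The median was 0.40 (camera adjusted p = 1.76e-08, adjusted p = 0.257 with an estimated correlation), with valS1 (DDB_G0277733, log2 fold change 1.06 ± 0.18, edgeR adjusted p = 0.000523) among them. Complexes II to IV and cytochrome c had 13 of 17 members higher and 1 lower (14 and 1 adjusted over the list alone). The median was 0.60 (camera adjusted p = 1.66e-07, adjusted p = 0.257 with an estimated correlation), with cxfA (DDB_G0282097, log2 fold change 1.13 ± 0.16, edgeR adjusted p = 0.000118) among the higher members. Glycolysis had 6 of 14 members higher and 1 lower (7 and 1 adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.000339, adjusted p = 0.257 with an estimated correlation). Its leading members were pyk (DDB_G0283247, log2 fold change 0.87 ± 0.14, edgeR adjusted p = 0.000425), gpdA (DDB_G0275153, 0.73 ± 0.12, adjusted p = 0.000436) and fba (DDB_G0274375, 0.89 ± 0.17, adjusted p = 0.00147), which encode pyruvate kinase, glyceraldehyde-3-phosphate dehydrogenase and aldolase.

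Sterol and isoprenoid synthesis, a pathway with several steps that use oxygen, had 6 of 16 members higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.000716, adjusted p = 0.257 with an estimated correlation). Its members included sqle (DDB_G0293584, 140 against 42.6 CPM, log2 fold change 1.72 ± 0.40, edgeR adjusted p = 0.00679), squalene monooxygenase, ebp (DDB_G0269414, 0.85 ± 0.14, adjusted p = 0.00047), and hmgB (DDB_G0276615, 0.74 ± 0.17, adjusted p = 0.00678), HMG-CoA reductase. CYP51 (DDB_G0279403, 1169 against 297 CPM, log2 fold change 1.98 ± 0.31, edgeR adjusted p = 0.000302), a sterol demethylase, was higher while the list of cytochrome P450 had 3 of 30 members higher and 8 lower (3 and 13 adjusted over the list alone). The median was -0.60 (camera adjusted p = 0.00289, adjusted p = 0.257 with an estimated correlation). Iron and heme genes had 8 of 13 members higher and 0 lower (9 and 0 adjusted over the list alone). The median was 0.68 (camera adjusted p = 0.000295, adjusted p = 0.291 with an estimated correlation). Among them hemA (DDB_G0280763, log2 fold change 1.85 ± 0.31, edgeR adjusted p = 0.000608) and hemF (DDB_G0288893, 1.98 ± 0.37, adjusted p = 0.00144) encode enzymes of heme synthesis, and fxn (DDB_G0293246, 1.01 ± 0.17, adjusted p = 0.00056) encodes frataxin.

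Discoidins, lectins made by starving or dense cells, had 0 of 7 members higher and 5 lower (0 and 7 adjusted over the list alone). The median was -1.19 (camera adjusted p = 0.000489, adjusted p = 0.36 with an estimated correlation), led by dscE (DDB_G0292552, log2 fold change -1.67 ± 0.25, edgeR adjusted p = 0.000243). Some members are close copies with nearly equal values, such as dscC-1 and dscC-2 (log2 fold change -1.55 and -1.52).

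At 5 h, 1738 genes changed, 912 higher and 826 lower, and 829 of them at least 2-fold (edgeR adjusted p under 0.05). Scaled by total counts, 41.1% of called genes were higher in place of 52.5%. Camera called 22 of 40 lists, 15 higher and 7 lower, while wrong groupings called up to 17 against 21 for the real one. Without t0 replicate 2, hypoxia 5 h replicate 2 or t0 replicate 3 the count of changed genes was 1070, 1104 and 1114. Lost without t0 replicate 1 were glycogen and trehalose (camera adjusted p = 0.0777), complex I (0.108), DNA replication (0.11) and mitosis (0.117). Calls lost without hypoxia 5 h replicate 1 were glycogen and trehalose (camera adjusted p = 0.269), DNA replication (0.693), mitosis (0.432), secreted density factors (0.0591) and mitochondrial import and quality (0.119). With total-count scaling, calls were lost for glycogen and trehalose (camera adjusted p = 0.0622), DNA replication (0.0769), mitosis (0.101) and mitochondrial import and quality (0.09). Lost with RLE size factors were mitochondrial import and quality (camera adjusted p = 0.0513). Calls lost without t0 replicate 3 were mitochondrial import and quality (camera adjusted p = 0.0899).

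After a day of low oxygen the question was what a sustained exposure changes, asked by hypoxia 24 h against t0 (n = 3 per group). Among named genes with a symbol, rabR (log2 fold change 8.66 ± 0.93, edgeR adjusted p = 1.27e-06) was again the largest rise, followed by genes of ponticulin-like proteins, which anchor actin at the membrane, namely ponC4 (DDB_G0286719, 136 against 0.767 CPM, 7.45 ± 0.32, adjusted p = 7.12e-11), ponC2 (DDB_G0286715, 7.18 ± 0.60, adjusted p = 6.94e-08) and ponC3 (DDB_G0286721, 53.8 against 0.47 CPM, 6.92 ± 0.48, adjusted p = 1.23e-08). Falls were largest for 3B-1 (DDB_G0272795, 0.553 against 29.6 CPM, log2 fold change -5.70 ± 0.91, edgeR adjusted p = 7.25e-05), 3B-2 (DDB_G0274045, -5.45 ± 0.91, adjusted p = 0.000106), annotated as prespore-specific, and for cf50-2 (DDB_G0273875, 1.75 against 78.2 CPM, -5.34 ± 0.53, adjusted p = 5.08e-07) and cf50-1 (DDB_G0273175, -5.27 ± 0.55, adjusted p = 8.91e-07), components of the counting factor that limits group size. The largest change without a symbol was DDB_G0290839 (log2 fold change 8.58 ± 1.00, edgeR adjusted p = 2.7e-06). rabR stood at 9.91 and ponC3 at 6.31 without t0 replicate 1. Without hypoxia 24 h replicate 3, 3B-2 stood at -6.19. How tags of such close copies were shared between them is not given.

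At 24 h, cxgE (log2 fold change -2.24 ± 0.20, edgeR adjusted p = 1.32e-07) remained lower and cxgS (2.48 ± 0.32, adjusted p = 8.03e-06) higher. Flavohemoglobin genes remained higher as fhbA (log2 fold change 3.25 ± 0.59, edgeR adjusted p = 0.00024) and fhbB (2.98 ± 0.50, adjusted p = 0.000112), at 4.78 and 4.36 without t0 replicate 1. By this time the alternative oxidase gene aoxA (log2 fold change -2.42 ± 0.52, edgeR adjusted p = 0.00108) was lower, and stood at -1.24 without t0 replicate 1 (edgeR adjusted p = 0.0141). Of the Skp1 pathway, phyA (log2 fold change -1.34 ± 0.32, edgeR adjusted p = 0.00236) and gnt1 (DDB_G0275699, -1.08 ± 0.30, adjusted p = 0.00731), a glycosyltransferase, were lower, fpaA (DDB_G0269230, 0.40 ± 0.12, adjusted p = 0.0123) was higher, and pgtA (DDB_G0283761, -0.11 ± 0.23, adjusted p = 0.724), fpaB-1 (DDB_G0273251, -0.25 ± 0.14, adjusted p = 0.148) and fpaB-2 (DDB_G0273615, -0.19 ± 0.12, adjusted p = 0.226) did not pass. fpaA lost its call without t0 replicate 2 (0.34, edgeR adjusted p = 0.0612). Of the oxygen panel, 4 of 11 members rose and 4 fell, the same over the list alone, and its median of -0.19 differed in sign from its mean of 0.13 (camera adjusted p = 0.932 downward). hydA (log2 fold change -3.48 ± 0.23, edgeR adjusted p = 9.5e-09) was lower.

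Actins had 26 of 31 members higher and 1 lower (26 and 2 adjusted over the list alone). The median was 1.42 (camera adjusted p = 5.13e-08, adjusted p = 0.483 with an estimated correlation), with act25 (DDB_G0289507, log2 fold change 4.27 ± 0.28, edgeR adjusted p = 7.2e-09) and act3 (DDB_G0289487, 3.51 ± 0.27, adjusted p = 3.33e-08) as examples. Cytoskeleton regulators, a list that holds the ponC genes, had 39 of 59 members higher and 3 lower (41 and 3 adjusted over the list alone). The median was 0.66 (camera adjusted p = 5.18e-08, adjusted p = 0.483 with an estimated correlation). Subunits of NADPH oxidases, which make superoxide, had 5 of 5 members higher and 0 lower (5 and 0 adjusted over the list alone). The median was 1.93 (camera adjusted p = 0.00733, adjusted p = 0.483 with an estimated correlation), among them cybA (DDB_G0267460, log2 fold change 1.87 ± 0.20, edgeR adjusted p = 9.59e-07), ncfA (DDB_G0288773, 1.93 ± 0.27, adjusted p = 1.75e-05) and noxB (DDB_G0287101, 2.19 ± 0.38, adjusted p = 0.000171). Discoidins had 4 of 7 members higher and 0 lower (4 and 0 adjusted over the list alone). The median was 2.73 (camera adjusted p = 0.00601, adjusted p = 0.584 with an estimated correlation), led by dscA-1 (DDB_G0273063, 2625 against 272 CPM, log2 fold change 3.27 ± 0.33, edgeR adjusted p = 6.13e-07). The proteasome had 25 of 42 members higher and 1 lower (26 and 1 adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.000296, adjusted p = 0.584 with an estimated correlation), with psmD10 (DDB_G0289189, log2 fold change 1.70 ± 0.25, edgeR adjusted p = 2.66e-05). tpsA (DDB_G0287657, 51.9 against 2.98 CPM, log2 fold change 4.12 ± 0.32, edgeR adjusted p = 4.62e-08), trehalose phosphate synthase, was higher.

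Cytosolic ribosomal proteins were lower, with 0 of 80 members higher and 41 lower (0 and 43 adjusted over the list alone). The median was -0.42 (camera adjusted p = 4.22e-06, adjusted p = 0.751 with an estimated correlation), for example rpl4 (DDB_G0277803, log2 fold change -0.76 ± 0.14, edgeR adjusted p = 0.000335). Vacuolar ATPase subunits, which acidify endosomes, had 0 of 10 members higher and 10 lower (0 and 10 adjusted over the list alone). The median was -0.81 (camera adjusted p = 0.000133, adjusted p = 0.483 with an estimated correlation), led by vatB (DDB_G0277401, log2 fold change -1.21 ± 0.14, edgeR adjusted p = 2.43e-06). Lysosomal enzymes had 6 of 32 members higher and 14 lower (6 and 15 adjusted over the list alone). The median was -0.60 (camera adjusted p = 0.00871, adjusted p = 0.483 with an estimated correlation), with cprD (DDB_G0278721, log2 fold change -2.65 ± 0.18, edgeR adjusted p = 1.2e-08), a cysteine protease, and alyL (DDB_G0286229, -3.05 ± 0.24, adjusted p = 5.29e-08). DNA replication genes had 1 of 40 members higher and 21 lower (1 and 27 adjusted over the list alone). The median was -0.80 (camera adjusted p = 0.000442, adjusted p = 0.741 with an estimated correlation), among them rnrA (DDB_G0284071, log2 fold change -1.38 ± 0.28, edgeR adjusted p = 0.000733), ribonucleotide reductase, and orcB (DDB_G0269894, -0.83 ± 0.16, adjusted p = 0.000363), while orcE (DDB_G0293214, 1.15 ± 0.22, adjusted p = 0.000412) was higher.

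Sterol and isoprenoid synthesis had 3 of 16 members higher and 10 lower (3 and 10 adjusted over the list alone). The median was -0.58 (camera adjusted p = 0.0131, adjusted p = 0.483 with an estimated correlation), with ebp (log2 fold change -1.48 ± 0.14, edgeR adjusted p = 3.2e-07) and erg24 (DDB_G0284407, -1.39 ± 0.16, adjusted p = 2.41e-06) as examples. Secreted density factors had 1 of 14 members higher and 10 lower (1 and 11 adjusted over the list alone). The median was -1.43 (camera adjusted p = 2.09e-05, adjusted p = 0.483 with an estimated correlation), including ctnA (DDB_G0274597, 182 against 2919 CPM, log2 fold change -4.01 ± 0.29, edgeR adjusted p = 1.77e-08), smlA (-3.60 ± 0.25, adjusted p = 1.2e-08) and cfaD (DDB_G0281605, -1.89 ± 0.14, adjusted p = 2.37e-08).

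At 24 h, 4690 genes changed, 2467 higher and 2223 lower, and 2655 of them at least 2-fold (edgeR adjusted p under 0.05). Camera called 14 of 40 lists, 7 higher and 7 lower, while wrong groupings called up to 11 against 14 for the real one. Autophagy genes had 7 of 12 members higher and 1 lower (7 and 1 adjusted over the list alone). The median was 0.86 (camera adjusted p = 0.0331, adjusted p = 0.483 with an estimated correlation), with atg1 (DDB_G0292390, log2 fold change 1.19 ± 0.18, edgeR adjusted p = 3.43e-05) and atg8 (DDB_G0286191, 1.91 ± 0.30, adjusted p = 5.14e-05), which stood at 1.27 without hypoxia 24 h replicate 1. In ribosome biogenesis the lowest adjusted p fell to rrpB (DDB_G0291249, log2 fold change 1.17 ± 0.19, edgeR adjusted p = 6.84e-05) and rrpA (DDB_G0289659, 1.11 ± 0.19, adjusted p = 0.000144), RNA-directed RNA polymerases that do not make ribosomes, and the list had 2 of 49 members higher and 11 lower (2 and 6 adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.0331, adjusted p = 0.764 with an estimated correlation), and fry did not call the list (adjusted p = 0.197). Without t0 replicate 1, calls were lost for ribosome biogenesis (camera adjusted p = 0.203) and autophagy (0.0823). Lost without hypoxia 24 h replicate 1 were ribosome biogenesis (camera adjusted p = 0.145).

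**Figure D3:**
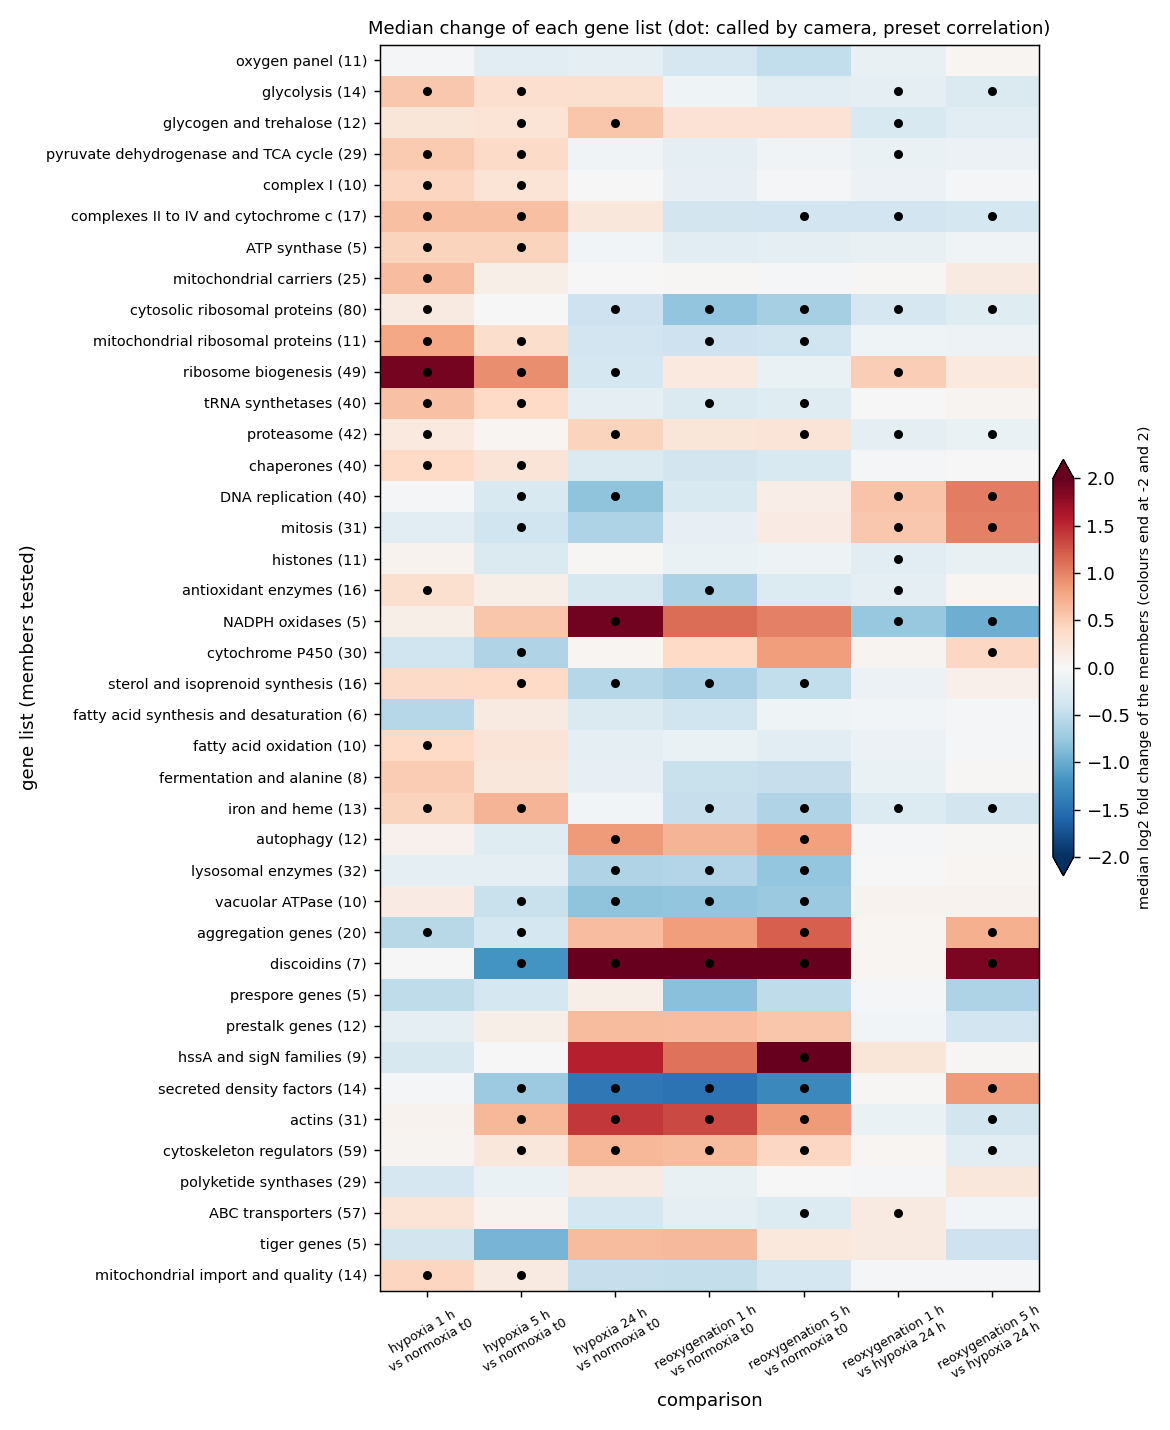
Median log2 fold change of 40 gene lists in the 7 comparisons, with colours ending at -2 and 2. Dots mark lists called by camera with the preset correlation, none of which held with an estimated correlation. With scaling by total counts, which moved the median of all genes by -0.17 at hypoxia 1 h and by 0.19 and 0.15 at reoxygenation 1 and 5 h against hypoxia 24 h, medians near 0 crossed it along with that shift, from negative to positive for glycolysis, pyruvate dehydrogenase and TCA cycle, proteasome and antioxidant enzymes at reoxygenation 1 h against hypoxia 24 h and for proteasome at reoxygenation 5 h against hypoxia 24 h, and from positive to negative for cytosolic ribosomal proteins at hypoxia 1 h.

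Reoxygenation 1 h against t0 asked what differed from the start once oxygen had been back for 1 h (n = 3 per group). Ponticulin-like genes were highest, with ponC4 (log2 fold change 7.59 ± 0.32, edgeR adjusted p = 5.33e-11), ponC2 (7.26 ± 0.59, adjusted p = 5.34e-08) and ponC5 (DDB_G0286723, 6.97 ± 0.53, adjusted p = 2.81e-08), next to arrK (DDB_G0280633, 64 against 0.455 CPM, 7.08 ± 0.56, adjusted p = 4.13e-08), related to ADP-ribosylation factors. The lowest were cf50-1 (log2 fold change -5.09 ± 0.54, edgeR adjusted p = 8.56e-07), cf50-2 (-5.09 ± 0.51, adjusted p = 5.15e-07), 3B-2 (-4.97 ± 0.84, adjusted p = 0.00012) and 3B-1 (-4.94 ± 0.82, adjusted p = 0.000101). The largest change without a symbol was DDB_G0291706, with 864 counts against 2 and a ratio per total counts of 503 (95% interval 139 to 4160 for counting error alone). Its log2 fold change was 8.44 ± 1.27 and 7.76 without t0 replicate 1. Both t0 counts lay in replicate 2, without which the t0 group held 0 counts and the fold has no exact size. ponC5 stood at 7.69 without t0 replicate 1.

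In the oxygen panel 1 h after oxygen returned, cxgS (log2 fold change 1.36 ± 0.31, edgeR adjusted p = 0.00174) was still above t0 and cxgE (-1.07 ± 0.19, adjusted p = 0.000176) still below it. fhbB (log2 fold change -2.08 ± 0.50, edgeR adjusted p = 0.00255) and aoxA (-2.72 ± 0.53, adjusted p = 0.000434) were below t0, but without t0 replicate 1 they stood at -0.69 (edgeR adjusted p = 0.0519) and -1.53. fhbA (log2 fold change 1.31 ± 0.55, edgeR adjusted p = 0.0635) did not pass, and passed without t0 replicate 1 (2.85, edgeR adjusted p = 4.87e-05). The Skp1 hydroxylase gene phyA (log2 fold change -1.77 ± 0.33, edgeR adjusted p = 0.000265) was lower. fpaA (log2 fold change 0.41 ± 0.12, edgeR adjusted p = 0.00999) was called higher and fpaB-2 (-0.34 ± 0.12, adjusted p = 0.0362) lower. The edgeR adjusted p was 0.0531 without t0 replicate 2 for fpaA, and for fpaB-2 0.0521 to 0.131 without any 1 of the 6 libraries compared except t0 replicate 3. Of 11 panel members, 2 rose and 5 fell, 3 and 6 adjusted over the list alone.

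Cytosolic ribosomal proteins had 0 of 80 members higher and 75 lower (0 and 76 adjusted over the list alone) at 1 h of reoxygenation, and a median of -0.78 (camera adjusted p = 8.66e-17, adjusted p = 0.558 with an estimated correlation). Actins had 23 of 31 members higher and 3 lower (23 and 3 adjusted over the list alone). The median was 1.32 (camera adjusted p = 5.64e-08, adjusted p = 0.47 with an estimated correlation).

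In this comparison 4439 genes changed, 2334 higher and 2105 lower, and 2499 of them at least 2-fold (edgeR adjusted p under 0.05). With scaling by total counts, 70.8% of called genes were higher in place of 52.6%, and the median of all genes shifted by 0.25. Camera called 12 of 40 lists, 3 higher and 9 lower, while wrong groupings called up to 13 against 14 for the real one. Calls lost without t0 replicate 1 were mitochondrial ribosomal proteins (camera adjusted p = 0.075), tRNA synthetases (0.0754) and iron and heme (0.0754). With total-count scaling, calls were lost for mitochondrial ribosomal proteins (camera adjusted p = 0.132) and tRNA synthetases (0.196). Lost without reoxygenation 1 h replicate 1 were tRNA synthetases (camera adjusted p = 0.1) and iron and heme (0.0673). Calls lost without reoxygenation 1 h replicate 3 were iron and heme (camera adjusted p = 0.0681).

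Reoxygenation 5 h against t0 asked what still differed from the start after 5 h of oxygen (n = 3 per group). The largest rises were ponC4 (log2 fold change 7.64 ± 0.32, edgeR adjusted p = 4.8e-11), arrK (85.8 against 0.455 CPM, 7.50 ± 0.56, adjusted p = 3.44e-08), ponC1 (DDB_G0286717, 7.26 ± 0.38, adjusted p = 4.95e-10) and ponC5 (7.15 ± 0.53, adjusted p = 3.3e-08), and ponC5 stood at 7.87 without t0 replicate 1. The largest falls were samkB (log2 fold change -5.61 ± 0.91, edgeR adjusted p = 9.28e-05), the lysozyme genes alyB (DDB_G0275119, 4.99 against 66.1 CPM, -3.74 ± 0.46, adjusted p = 6.69e-06) and alyA (DDB_G0275123, -3.68 ± 0.49, adjusted p = 1.35e-05), and grlB (DDB_G0271686, 1.77 against 20.3 CPM, -3.47 ± 0.47, adjusted p = 1.65e-05), a family 3 G-protein-coupled receptor. DDB_G0267896 (321 against 1.33 CPM, log2 fold change 7.90 ± 0.45, edgeR adjusted p = 1.52e-09) was the largest change without a symbol. Both oxidase isoforms had moved back, with cxgE (log2 fold change 0.32 ± 0.19, edgeR adjusted p = 0.194) no longer apart from t0 and cxgS (-2.78 ± 0.34, adjusted p = 5.11e-06) below it.

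Flavohemoglobin genes were below t0 after 5 h of oxygen, fhbB (log2 fold change -2.56 ± 0.51, edgeR adjusted p = 0.000702) and fhbA (-2.51 ± 0.59, adjusted p = 0.00257), but stood at -1.17 and at -0.98 (edgeR adjusted p = 0.0595) without t0 replicate 1. aoxA (log2 fold change -0.49 ± 0.49, edgeR adjusted p = 0.464) did not pass. phyA (log2 fold change -1.07 ± 0.31, edgeR adjusted p = 0.0114) lost its call in some settings, with an edgeR adjusted p of 0.0657 without reoxygenation 5 h replicate 1 and 0.0738 without t0 replicate 2. For the only rise, fpaA (log2 fold change 0.34 ± 0.12, edgeR adjusted p = 0.0328), the edgeR adjusted p was 0.0535 to 0.131 without any 1 of the 6 libraries compared except reoxygenation 5 h replicate 3. Of 11 panel members, 1 rose and 4 fell, the same over the list alone.

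Discoidins had 7 of 7 members higher and 0 lower (7 and 0 adjusted over the list alone) after 5 h of oxygen, at a median of 4.01 (camera adjusted p = 2.24e-06, adjusted p = 0.435 with an estimated correlation). Aggregation genes had 12 of 20 members higher and 2 lower (13 and 2 adjusted over the list alone). The median was 1.20 (camera adjusted p = 0.0018, adjusted p = 0.435 with an estimated correlation). Cytosolic ribosomal proteins remained lower, with 0 of 80 members higher and 63 lower (0 and 69 adjusted over the list alone). The median was -0.67 (camera adjusted p = 3.12e-15, adjusted p = 0.435 with an estimated correlation). Actins had 20 of 31 members higher and 1 lower (20 and 2 adjusted over the list alone). The median was 0.85 (camera adjusted p = 2.24e-06, adjusted p = 0.435 with an estimated correlation).

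In total 4004 genes differed from t0 after 5 h of oxygen, 2105 higher and 1899 lower, and 2235 of them at least 2-fold (edgeR adjusted p under 0.05). Under scaling by total counts, 70.1% of called genes were higher in place of 52.6%, and the median of all genes shifted by 0.21. Camera called 17 of 40 lists, 7 higher and 10 lower, while wrong groupings called up to 19 against 13 for the real one, and 4 of 10 splits reached the real count. Without reoxygenation 5 h replicate 1, calls were lost for complexes II to IV and cytochrome c (camera adjusted p = 0.0837), tRNA synthetases (0.165), iron and heme (0.0837) and ABC transporters (0.0528). Lost without t0 replicate 3 were complexes II to IV and cytochrome c (camera adjusted p = 0.0513) and ABC transporters (0.0539). Calls lost with total-count scaling were complexes II to IV and cytochrome c (camera adjusted p = 0.0817), mitochondrial ribosomal proteins (0.0501), tRNA synthetases (0.235), hssA and sigN families (0.0639) and ABC transporters (0.0501). Without t0 replicate 1, calls were lost for tRNA synthetases (camera adjusted p = 0.101) and ABC transporters (0.0708). Lost without reoxygenation 5 h replicate 3 were tRNA synthetases (camera adjusted p = 0.0668). Calls lost with no filter on low counts were hssA and sigN families (camera adjusted p = 0.262). Without reoxygenation 5 h replicate 2, calls were lost for ABC transporters (camera adjusted p = 0.061).

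Reoxygenation 1 h against hypoxia 24 h asked what the return of oxygen changes first (n = 3 per group). The largest falls were rabR (log2 fold change -8.00 ± 0.89, edgeR adjusted p = 5.61e-05), fhbB (-5.05 ± 0.56, adjusted p = 5.61e-05), srsA (-4.89 ± 1.07, adjusted p = 0.0136), warA (DDB_G0291075, 7.93 against 68.2 CPM, -3.10 ± 0.46, adjusted p = 0.000594), a homeobox gene, and DDB_G0276271 (1.82 against 170 CPM, -6.51 ± 0.83, adjusted p = 0.000156). cxgE (log2 fold change 1.17 ± 0.19, edgeR adjusted p = 0.00152) was higher and cxgS (-1.13 ± 0.31, adjusted p = 0.048) lower. fhbA (log2 fold change -1.94 ± 0.56, edgeR adjusted p = 0.0612) and aoxA (-0.30 ± 0.51, adjusted p = 0.831) did not pass. Besides cxgE, the largest rises were iptA (DDB_G0277215, 16.3 against 7.05 CPM, log2 fold change 1.28 ± 0.34, edgeR adjusted p = 0.0441), CYP508B1 (DDB_G0282419, 34 against 15 CPM, 1.20 ± 0.33, adjusted p = 0.0466) and tmcB (DDB_G0289207, 20.3 against 9.66 CPM, 1.09 ± 0.27, adjusted p = 0.0317). Without reoxygenation 1 h replicate 3, rabR stood at -9.00 and DDB_G0276271 at -7.58. Several of these calls passed narrowly and were lost with fewer libraries, while in the fits that lost them the log2 fold change stayed at -1.26 to -0.98 for cxgS, -4.82 to -4.58 for srsA, 0.91 to 1.36 for iptA, 0.92 to 1.23 for CYP508B1 and 0.80 to 1.13 for tmcB. For cxgS the edgeR adjusted p was 0.0609 to 0.21 without any 1 of the 6 libraries compared. For srsA it was 0.0841 without reoxygenation 1 h replicate 1 and 0.0503 without reoxygenation 1 h replicate 2. For iptA it was 0.116 without reoxygenation 1 h replicate 1, 0.185 without hypoxia 24 h replicate 2, 0.0584 without reoxygenation 1 h replicate 2, 0.187 without hypoxia 24 h replicate 3 and 0.128 without reoxygenation 1 h replicate 3, and the log2 fold change was 1.95 without hypoxia 24 h replicate 1. For CYP508B1 it was 0.113 without reoxygenation 1 h replicate 1, 0.167 without hypoxia 24 h replicate 2, 0.185 without hypoxia 24 h replicate 3 and 0.194 without reoxygenation 1 h replicate 3, and for tmcB 0.0854 without reoxygenation 1 h replicate 1, 0.0908 without hypoxia 24 h replicate 2, 0.15 without hypoxia 24 h replicate 3 and 0.159 without reoxygenation 1 h replicate 3. Of the oxygen panel, 1 of 11 members rose and 2 fell, 1 and 3 adjusted over the list alone.

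Ribosome biogenesis was called higher by camera but not by fry (adjusted p = 0.0511) 1 h after oxygen returned, with 8 of 49 members higher and 0 lower (22 and 0 adjusted over the list alone). The median was 0.50 (camera adjusted p = 1.37e-12, adjusted p = 0.432 with an estimated correlation). Complexes II to IV and cytochrome c had 1 of 17 members higher and 5 lower (1 and 10 adjusted over the list alone). The median was -0.39 (camera adjusted p = 3.22e-06, adjusted p = 0.432 with an estimated correlation). Iron and heme genes had 0 of 13 members higher and 5 lower (0 and 5 adjusted over the list alone). The median was -0.27 (camera adjusted p = 2.01e-05, adjusted p = 0.432 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 80 members higher and 0 lower (0 and 0 adjusted over the list alone). The median was -0.34 (camera adjusted p = 5.47e-17, adjusted p = 0.721 with an estimated correlation), and fry did not call the list (adjusted p = 0.138).

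At 1 h after oxygen returned, 407 genes changed, 107 higher and 300 lower, and 261 of them at least 2-fold (edgeR adjusted p under 0.05). Scaled by total counts, 55.8% of called genes were higher in place of 26.3%, and the median of all genes shifted by 0.19. The count was 167 without reoxygenation 1 h replicate 1, 198 without its replicate 3, 221 without hypoxia 24 h replicate 2 and 208 without hypoxia 24 h replicate 3. Camera called 14 of 40 lists, 4 higher and 10 lower, while wrong groupings of the same libraries called up to 12 against 11 for the real one, and 3 of 10 splits reached the real count. Lost without hypoxia 24 h replicate 1 were glycolysis (camera adjusted p = 0.118), histones (0.421), NADPH oxidases (0.0756) and ABC transporters (0.172). Calls lost without reoxygenation 1 h replicate 1 were pyruvate dehydrogenase and TCA cycle (camera adjusted p = 0.523), histones (0.053) and ABC transporters (0.103). Without hypoxia 24 h replicate 2, calls were lost for pyruvate dehydrogenase and TCA cycle (camera adjusted p = 0.0686). Lost without hypoxia 24 h replicate 3 were pyruvate dehydrogenase and TCA cycle (camera adjusted p = 0.0835) and ABC transporters (0.0545). Calls lost without reoxygenation 1 h replicate 3 were histones (camera adjusted p = 0.129) and ABC transporters (0.148). With total-count scaling, calls were lost for histones (camera adjusted p = 0.0592) and ABC transporters (0.11). Lost without reoxygenation 1 h replicate 2 were NADPH oxidases (camera adjusted p = 0.113). Calls lost with no filter on low counts were ABC transporters (camera adjusted p = 0.055). With total-count scaling, medians near 0 crossed it along with the shift of all genes for glycolysis (median 0.02, camera adjusted p = 0.0947), pyruvate dehydrogenase and TCA cycle (median 0.07, camera adjusted p = 0.672), proteasome (median 0.02, camera adjusted p = 0.0137) and antioxidant enzymes (median 0.02, camera adjusted p = 0.00814).

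Reoxygenation 5 h against hypoxia 24 h asked which hypoxia levels were left behind after 5 h of oxygen (n = 3 per group). The largest falls were rabR (log2 fold change -8.85 ± 0.95, edgeR adjusted p = 1.03e-05), srsA (-8.10 ± 1.25, adjusted p = 0.000377), fhbA (-5.76 ± 0.67, adjusted p = 2.33e-05), fhbB (-5.54 ± 0.57, adjusted p = 7.72e-06) and, without a symbol, DDB_G0290839 (-8.26 ± 0.97, adjusted p = 2.6e-05). cxgS (log2 fold change -5.26 ± 0.37, edgeR adjusted p = 9.85e-08) fell and cxgE (2.56 ± 0.20, adjusted p = 3.4e-07) rose. The largest rises were cad3 (DDB_G0285817, 321 against 11.7 CPM, log2 fold change 4.78 ± 0.47, edgeR adjusted p = 5.22e-06), the P450 genes CYP516B1 (DDB_G0271778, 48.4 against 2.03 CPM, 4.59 ± 0.55, adjusted p = 3.14e-05) and CYP519E1 (DDB_G0286419, 25.8 against 1.32 CPM, 4.25 ± 0.53, adjusted p = 5.1e-05), and prtB (DDB_G0271666, 55.8 against 6.17 CPM, 3.17 ± 0.53, adjusted p = 0.000699). Without reoxygenation 5 h replicate 1 these stood at 4.16, 3.87, 3.44 and 2.55.

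Smaller moves after 5 h of oxygen included aoxA (log2 fold change 1.94 ± 0.52, edgeR adjusted p = 0.0214), whose edgeR adjusted p was 0.0868 without hypoxia 24 h replicate 1, 0.0529 without hypoxia 24 h replicate 2, 0.0556 without reoxygenation 5 h replicate 2 and 0.0628 without reoxygenation 5 h replicate 3. hydA (log2 fold change 2.67 ± 0.23, edgeR adjusted p = 9.28e-07) rose and sodE (18.8 against 88.5 CPM, -2.23 ± 0.23, adjusted p = 7.72e-06) fell. CYP51 (log2 fold change -2.01 ± 0.31, edgeR adjusted p = 0.00035) and sqle (-2.15 ± 0.41, adjusted p = 0.00205) fell, while smt1 (DDB_G0288907, 0.86 ± 0.14, adjusted p = 0.000472), a sterol methyltransferase, rose, and the list of sterol and isoprenoid synthesis was not called (median 0.10, mean -0.29, camera adjusted p = 0.677 downward). Of the oxygen panel, 2 of 11 members rose and 3 fell, the same over the list alone, and its median of 0.03 differed in sign from its mean of -1.03 (camera adjusted p = 0.454 downward).

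DNA replication genes were called higher by camera but not by fry (adjusted p = 0.07) after 5 h of oxygen, with 17 of 40 members higher and 1 lower (23 and 1 adjusted over the list alone). The median was 1.02 (camera adjusted p = 1.42e-08, adjusted p = 0.573 with an estimated correlation). Examples were pcna (DDB_G0287607, log2 fold change 1.40 ± 0.28, edgeR adjusted p = 0.00324), the sliding clamp of DNA polymerase, and rnrA (1.36 ± 0.28, adjusted p = 0.00421). Mitosis genes, also not called by fry (adjusted p = 0.0923), had 9 of 31 members higher and 0 lower (20 and 0 adjusted over the list alone). The median was 1.01 (camera adjusted p = 5.49e-06, adjusted p = 0.595 with an estimated correlation), led by smc3 (DDB_G0276101, log2 fold change 1.31 ± 0.32, edgeR adjusted p = 0.0118), a cohesin subunit, whose edgeR adjusted p was 0.0632 without hypoxia 24 h replicate 2 and 0.0704 without reoxygenation 5 h replicate 3. Secreted density factors had 8 of 14 members higher and 1 lower (9 and 1 adjusted over the list alone). The median was 0.86 (camera adjusted p = 5.49e-06, adjusted p = 0.297 with an estimated correlation), with ctnA (log2 fold change 1.97 ± 0.26, edgeR adjusted p = 9.02e-05), smlA (1.94 ± 0.23, adjusted p = 2.78e-05) and cf50-2 (2.71 ± 0.53, adjusted p = 0.00264). Discoidins had 5 of 7 members higher and 0 lower (7 and 0 adjusted over the list alone). The median was 1.89 (camera adjusted p = 5.49e-06, adjusted p = 0.346 with an estimated correlation), with dscE (log2 fold change 1.36 ± 0.25, edgeR adjusted p = 0.00145). Aggregation genes had 6 of 20 members higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.72 (camera adjusted p = 0.00116, adjusted p = 0.346 with an estimated correlation), led by csaA (DDB_G0289073, 29 against 4.12 CPM, log2 fold change 2.85 ± 0.42, edgeR adjusted p = 0.000247), an adhesion protein, and regA (DDB_G0284331, 1.11 ± 0.24, adjusted p = 0.00505), a cAMP phosphodiesterase.

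Lower after 5 h of oxygen were complexes II to IV and cytochrome c, with 1 of 17 members higher and 7 lower (1 and 9 adjusted over the list alone). The median was -0.36 (camera adjusted p = 5.49e-06, adjusted p = 0.297 with an estimated correlation), including cxeA (DDB_G0269118, log2 fold change -0.94 ± 0.13, edgeR adjusted p = 0.000125). Iron and heme genes had 0 of 13 members higher and 5 lower (1 and 6 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.00116, adjusted p = 0.382 with an estimated correlation), among them hemF (log2 fold change -2.66 ± 0.39, edgeR adjusted p = 0.000215), hemG (DDB_G0292040, -2.11 ± 0.27, adjusted p = 5.88e-05) and fxn (-1.47 ± 0.18, adjusted p = 2.73e-05). NADPH oxidases had 0 of 5 members higher and 3 lower (0 and 4 adjusted over the list alone). The median was -0.97 (camera adjusted p = 0.0114, adjusted p = 0.3 with an estimated correlation), with cybA (log2 fold change -0.86 ± 0.19, edgeR adjusted p = 0.00617).

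At 5 h after oxygen returned, 1000 genes changed, 546 higher and 454 lower, and 641 of them at least 2-fold (edgeR adjusted p under 0.05). With scaling by total counts, 69.4% of called genes were higher in place of 54.6%, and the median of all genes shifted by 0.15. The count was 662 without reoxygenation 5 h replicate 3. Camera called 14 of 40 lists, 6 higher and 8 lower, while wrong groupings called up to 13 against 15 for the real one. Without hypoxia 24 h replicate 1, calls were lost for proteasome (camera adjusted p = 0.109), actins (0.184) and cytoskeleton regulators (0.0545). Lost without reoxygenation 5 h replicate 1 were proteasome (camera adjusted p = 0.0577). Calls lost without reoxygenation 5 h replicate 3 were proteasome (camera adjusted p = 0.0522), actins (0.117) and cytoskeleton regulators (0.0522). With total-count scaling, medians near 0 crossed it along with the shift of all genes for proteasome (median 0.02, camera adjusted p = 0.339).

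In the authors' deposited table, 2682, 1910, 4449, 4130 and 3896 genes had an FDR under 0.05 against t0 at hypoxia 1, 5 and 24 h and reoxygenation 1 and 5 h. Of these, 2611, 1550, 4211, 3932 and 3629 were also called here by edgeR, all with the same sign, from the same counts. Their log2 fold changes and those computed here had Pearson correlations of 0.998 at 1 h and 0.999 at 5 h of hypoxia.

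Whether early hypoxia changes turn back with oxygen was asked by comparing hypoxia 5 h against t0 with reoxygenation 5 h against hypoxia 24 h, which share no library. Of the 1738 genes changed at 5 h, 380 (21.9%) changed the opposite way on reoxygenation by edgeR and 30 the same way. Without replicate 2 of every group the count of opposite changes was 117, and without replicate 3 it was 187. rabR, srsA, fhbA, fhbB, cxgS and sqle were among 201 genes that rose and then fell, where 40.2 were expected from independent lists. cxgE, smlA and hydA were among 179 that fell and then rose, where 43.8 were expected. Across genes, which are not independent replicates, the Spearman correlation of fold changes was -0.33.

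**Figure D4:**
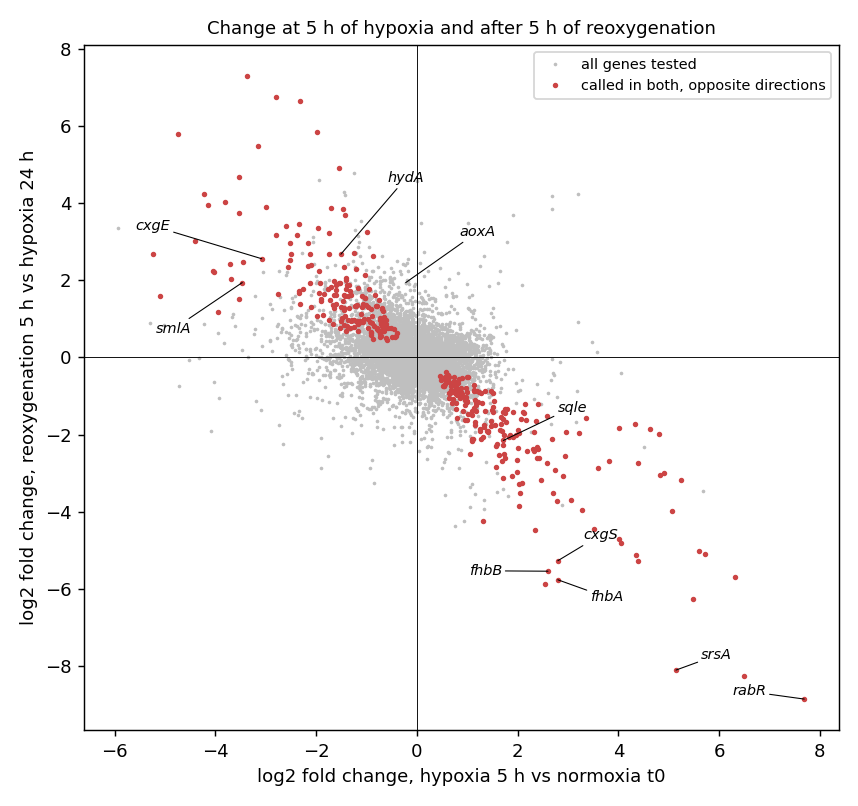
Log2 fold change of each gene at hypoxia 5 h against t0 and at reoxygenation 5 h against hypoxia 24 h. Red marks genes called in both comparisons with opposite signs. Labelled genes are rabR, srsA, fhbA, fhbB, cxgS, cxgE, sqle, aoxA, hydA and smlA, of which aoxA was not called at hypoxia 5 h.

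Whether 24 h changes persist was asked by comparing hypoxia 24 h and reoxygenation 5 h, each against t0. Of 4690 genes changed at 24 h, 3143 (67.0%) were still changed the same way after 5 h of oxygen by edgeR, 1699 higher and 1444 lower, and 2073 were without replicate 2 of every group. Independent lists would share 505 and 410. ponC4 was among those still higher and samkB, alyA and alyB among those still lower, whereas the test did not call cxgE against t0. Both comparisons use the same t0 libraries, and 20 simulations of unchanged groups gave a correlation of 0.494 on average and 0.516 at most, against 0.831 observed, and a covariance of 0.0493 on average and 0.0526 at most, against 1.3. The t0 group of 3 cannot be divided between the comparisons.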

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

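Ribosome biogenesis genes were lower at 24 h than at 1 h of hypoxia, with a median log2 difference of -2.40 (24 h against 1 h, 3 members higher and 46 lower, camera adjusted p = 1.18e-20, adjusted p = 0.286 with an estimated correlation). Between 5 h and 24 h the median difference was -1.23 (2 higher and 44 lower, camera adjusted p = 7.34e-13, adjusted p = 0.328 with an estimated correlation). Cytosolic ribosomal proteins stood at -0.57 at 24 h against 1 h (63 lower, camera adjusted p = 1.88e-08, adjusted p = 0.433 with an estimated correlation). aoxA, the alternative oxidase gene, stood at -4.83 at 24 h against 1 h (edgeR adjusted p = 1.73e-06). Sterol and isoprenoid synthesis genes stood at -0.80 at 24 h against 5 h (11 lower, camera adjusted p = 9.8e-05, adjusted p = 0.325 with an estimated correlation). Discoidins stood at 3.79 at 24 h against 5 h (7 higher, camera adjusted p = 3.56e-05, adjusted p = 0.328 with an estimated correlation). Each was called in opposite directions against t0 at the times compared, though for cytosolic ribosomal proteins at 1 h only 1 of 80 members was higher (0 adjusted over the list alone), and that call was lost without t0 replicate 1 (camera adjusted p = 0.112), t0 replicate 3 (0.064) or hypoxia 1 h replicate 2 (0.874, median -0.01) and with total-count scaling (0.375, median -0.02). For ribosome biogenesis at 24 h only 11 of 49 members were lower (6 adjusted over the list alone) and the call was lost without t0 replicate 1 (0.203) or hypoxia 24 h replicate 1 (0.145). These contrasts between hypoxia times were chosen only after the t0 comparisons had been seen.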

How the results depend on the processing

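Total-count scaling and leaving out single libraries for lists and named genes were chosen only after the results had been seen. With a minimum change of 2-fold, the calls were 1687, 829, 2655, 2499 and 2235 genes against t0 at hypoxia 1, 5 and 24 h and reoxygenation 1 and 5 h, 261 and 641 genes at reoxygenation 1 and 5 h against hypoxia 24 h, 4391 across the 6 groups and 1993 persisting. DESeq2 called 616 genes at reoxygenation 1 h against hypoxia 24 h. Fry called 27 lists at hypoxia 1 h, 23 at 24 h, 28 and 27 at reoxygenation 1 and 5 h against t0, and 6 at reoxygenation 1 h against hypoxia 24 h. Camera with an estimated correlation called 0 lists in each comparison, and with total-count scaling 11 lists at hypoxia 1 h. The cause of these shifts was not tested. Of 412 tests of named genes, 409 stayed on the same side of the adjusted p threshold with RLE size factors and 403 with no filter on low counts, as did 397 of 407 with DESeq2. The threshold was no longer passed by 92 without replicate 2, 67 without replicate 3 and 37 without replicate 1, whatever the size of the fold change.

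Leaving out replicate numbers or single libraries gave 1916 to 2954 changed genes at hypoxia 1 h, 420 to 1501 at 5 h and 3423 to 4326 at 24 h against t0. At reoxygenation the range was 3028 to 4298 at 1 h and 2728 to 3708 at 5 h against t0, and 94 to 429 at 1 h and 370 to 878 at 5 h against hypoxia 24 h. Across the 6 groups it was 5505 to 6178, for opposite changes 117 to 302 and for persisting changes 2073 to 2281. Lists called ranged from 9 to 14 at reoxygenation 1 h against hypoxia 24 h. Fewer libraries lower the power of every test, but some losses were uneven. Without replicate 1, 2 or 3 of every group, 1501, 420 and 647 genes changed at hypoxia 5 h, but 3423, 3478 and 3614 at 24 h.

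Replicate numbers are not stated to pair the libraries, and no comparison had every pair of equal numbers correlated above 0.1. The mean correlation was 0.068 for equal numbers and -0.034 for others, and 15 of 18 libraries correlated best with their own number, a hint from the data and not the design. With a replicate block, 3263, 1848, 4768, 4506 and 4088 genes were called against t0 and 470 and 1073 against hypoxia 24 h, in the order used above. With that replicate block camera no longer called mitosis at hypoxia 5 h (adjusted p = 0.0555) or ABC transporters at reoxygenation 5 h (0.0522) against t0, and called autophagy at reoxygenation 1 h against t0 (0.0482).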

Other observations

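mileS (DDB_G0293030, log2 fold change -1.84 ± 0.16, edgeR adjusted p = 1.19e-07), an isoleucyl-tRNA synthetase gene, hemB (DDB_G0269444, -1.37 ± 0.19, adjusted p = 1.82e-05), of heme synthesis, and adhfe1 (DDB_G0290111, -1.55 ± 0.21, adjusted p = 1.09e-05), an alcohol dehydrogenase, were lower after 24 h of hypoxia. dymA (DDB_G0277849, log2 fold change 1.36 ± 0.15, edgeR adjusted p = 1.65e-06), of a dynamin-like protein, and fbp (DDB_G0270836, 1.63 ± 0.19, adjusted p = 2.86e-06), the gluconeogenic fructose bisphosphatase, were higher. After 5 h of oxygen the prestalk gene ecmB (DDB_G0269132, log2 fold change -4.37 ± 0.59, edgeR adjusted p = 9.51e-05) and the desaturase gene fadA (DDB_G0285211, -1.20 ± 0.17, adjusted p = 0.000142) were lower than at hypoxia 24 h.

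Tags of genes annotated as non-coding RNA made up 0.209% of counts in hypoxia 1 h replicate 2 (95% Wilson interval 0.205% to 0.214%) and 0.372% in t0 replicate 1 (0.369% to 0.376%), the ends of the range among t0, hypoxia 1 h and 5 h. From hypoxia 24 h on the range was 0.885% in reoxygenation 5 h replicate 3 (0.879% to 0.891%) to 1.81% in reoxygenation 1 h replicate 1 (1.80% to 1.82%).

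Of the tests below, all but the separate-control overlap and the correlation with the fall on reoxygenation were chosen only after the result was seen. The rise of ribosome biogenesis genes at hypoxia 1 h might come from the shallow library, scaling or handling. Without hypoxia 1 h replicate 2 the median was 1.97, which argues against the first. Total-count scaling gave 1.73, with 46 of 49 members higher (edgeR), but moved the median gene by only -0.17, so scaling stays open. On handling, the median was 0.50 at reoxygenation 1 h against hypoxia 24 h, which leaves it open, as no handled culture was kept in normoxia. A hypothesis is that the rise follows handling and not low oxygen, which a mock transfer in normoxia for 1 h could test.

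The 24 h changes left after 5 h of oxygen could reflect shared t0 libraries, time in culture or a slow return. With separate controls, 2666 genes changed the same way at hypoxia 24 h against t0 and at reoxygenation 5 h against hypoxia 5 h, 2.35 times the 1130 of independent lists and between the bounds of 1.5 and 3 set beforehand, which leaves open how much the shared t0 libraries add. Of genes called at 24 h but not at 5 h of hypoxia, 8.5% changed the opposite way after 5 h of oxygen, against 38.9% of those changed the same way at both times, whose median change at 24 h was larger (1.51 against 1.08 in log2), which leaves time in culture open. The median share of the 24 h change left fell from 92.3% to 80.4% between 1 and 5 h of oxygen, by 11.9 points, and no later time was analysed here. A normoxic culture of 24 h would be the test.

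Hypoxia-responsive genes stood higher in t0 replicate 1 than in its replicates 2 and 3, which might come from stray reads or from less oxygen before sampling. Reads from a hypoxia library would add the same share to each gene, but rabR called for at most 2.86% of such a library and srsA for at least 5.89%, and the smallest ratio to the rabR share was 6.49, which argues against stray reads. For less oxygen, the correlation with the fall on reoxygenation was 0.10 over 407 genes, at the lower of the bounds of 0.1 and 0.3 set beforehand, with a Spearman rho of 0 over the same genes and Pearson correlations of -0.05 over all genes and, over the 407, of -0.09 and -0.06 for replicates 2 and 3, which leaves it open. Measuring oxygen in the t0 culture before sampling could test it.

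Other groupings checked that real groups gave more calls than wrong ones. In 10 splits of each 6 libraries, every wrong one gave 0 changed genes against t0. The real one gave 2635, 1762, 4610, 4436 and 4179, in the order of the report. Against hypoxia 24 h it gave 393 (highest other 15) and 1145 (0). For lists, the real and highest other counts were 18 and 17, 21 and 17, 14 and 11, 14 and 13, and 13 and 19 against t0, and 11 and 12, and 15 and 13 against hypoxia 24 h, with 4 splits reaching the real count at reoxygenation 5 h against t0 and 3 at reoxygenation 1 h against hypoxia 24 h. Such splits are too few for a share under 0.05. In 100 regroupings of all libraries, 1 reached the real count of 7356 genes across groups (highest other 549), of 380 opposite changes (0) and of 3143 persisting changes (815). Mixing groups lowers any such count, so these do not test reversal or persistence.

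Hypoxia 24 h replicates 2 and 3 lay closer to each other than to replicate 1, a pattern tested earlier and not weighed above. Chi-square per degree of freedom was 2.76 between them, against 7.94 to 35.2 for other pairs within groups (23.6 and 25.9 with replicate 1). At 5684309 counts and over 6115 genes, the log2 distances of replicate 1 to replicates 2 and 3 were 0.513 and 0.53, against 0.207 between those. Without replicate 1, 3910 genes changed at hypoxia 24 h against t0 in place of 4690.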
